A study of Mus musculus with 8 samples.

How the data were processed

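The study measured N6-methyladenosine (m6A), a methyl mark on adenosines inside RNA, in primary hepatic stellate cells of the mouse. Stellate cells are the vitamin A storing pericytes of the liver, and they turn into matrix-producing myofibroblasts when placed in culture. Cells of control mice and of mice with a stellate cell knockout of Mettl3 (conditional knockout, cKO) were cultured for 7 days. Mettl3 encodes the catalytic subunit of the main m6A methyltransferase. According to the labels' protocols, 100 µg of total RNA per library was fragmented to 100 to 200 nucleotides and precipitated with an antibody against m6A. Libraries of precipitated and of input RNA were then read as 150-bp paired ends. The labels give 8 samples in 4 groups of 2, with input and precipitated RNA for each genotype.

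The authors deposited 2 peak lists, 1 for each genotype. Per the file headers, each peak carries a gene, exon blocks, a strand, a p-value, the log10 of that p-value, the log10 of a false discovery rate, an annotation class and a fold enrichment. The fold enrichment was read here as a ratio of precipitated over input RNA, which its column name does not spell out. The column named score in the deposited lists held the p-value itself. The log10 column of the deposited lists was treated here as a score because it runs to very large negative values. Where the p-value was above 0, it differed from the log10 of the p-value by at most 0.02. The submitters' processing notes name HISAT2, HOMER and the mm10 build without giving their roles. The peak caller, its settings and its handling of the replicates are not given in the sources used here. Because each list is 1 call for a genotype with no value per replicate, the spread between replicates could not be measured. Read depth is unknown for the same reason.

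Each peak was taken from its outer start to its outer end and split into its exon blocks. In the log10 p column, 57 control cells and 44 cKO cells held a spreadsheet error, and these peaks were ranked as having the smallest p. The corresponding cells of the false discovery rate numbered 313 and 222, all in peaks with a p of 0. Peaks of the 2 lists were called counterparts where their exon blocks shared at least 1 bp on the same strand (bedtools 2.31.1). Genes were joined by symbol, and older symbols were matched through a RefSeq gene table of the GRCm38 assembly, which is the mm10 build. Some symbols in the deposited lists had turned into spreadsheet dates, and these were joined and counted as they stood. Of the gene names, 4837 of 4986 in the control list and 4128 of 4300 in the cKO list were found in that table. Computation used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

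No p-value is given for any difference between the genotypes, because peaks and genes are not replicates. Shares are given with exact Clopper-Pearson 95% intervals, which cover counting error only. For 21 gene lists fixed before the data were examined, the share of genes with a control peak that also had a cKO peak was set against 10000 random lists. Random lists were matched on the number of control peaks (1, 2, 3, or 4 and more) and on the best control fold in 5 bins. The percentile among them describes these 2 peak lists and is no test of genotype. It is given only for lists with at least 5 genes with a control peak. RNA abundance was not analysed here, so random lists could not be matched on it, and a peak missing from a list can reflect a less abundant transcript. Fold enrichments were ranked within a list and not subtracted between lists.

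The overlap of peaks, the random-list percentile and the rank probability were tested on simulated data. All 2000 control peaks planted in a copy of the control list of 8397 peaks were found again. They had been shifted by far less than the narrowest peak width, so this checks the computation only. For lists of 40 genes drawn from the 4986 control genes, 2 of 100 unchanged lists fell outside percentiles 2.5 to 97.5, and 79 of 100 lists with 20 percentage points fewer genes in both lists fell below 2.5. Most fixed lists had fewer than 40 genes with a control peak, down to 7 for long non-coding RNAs. Smaller lists were not simulated. For simulated scores with a rank probability of 0.760, the estimate was 0.766.

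Named genes followed a rule fixed before the data were examined. It took Mettl3, Mettl14, Wtap and Lats2 and the 8 genes of highest fold found in 1 list alone, for each list. To these it added the 6 genes of best mean rank in both lists and the 5 genes with most control peaks. From each gene list it took up to 2 genes found in both lists, 2 found in the control list alone and 1 found in the cKO list alone, and predicted genes were passed over in the rankings. Not every gene that the rule takes is reported here. Other members of the gene lists are named as examples chosen after their values were seen. Alternatives changed the overlap required, the strand rule, the p and false discovery rate limits, list length, the fold range, the gene type and the matching of random lists. A motif search was planned and not run, because no genome sequence was used here.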

Results

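m6A peaks of control and Mettl3 cKO hepatic stellate cells were compared after 7 days of culture, during which the cells activate spontaneously. The question was how loss of the methyltransferase in stellate cells changes the set of methylated transcripts. The labels give 2 precipitated and 2 input libraries for each genotype, and the authors' peak list of each genotype was the unit of comparison. Control cells had 8397 peaks in 4986 genes, and cKO cells had 6709 peaks in 4300 genes. All positions are those of the mm10 build.

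m6A peaks were still called in number in the Mettl3 cKO cells, though fewer than in control cells. The peak number was 20.1% lower in the cKO list, the number of genes with a peak 13.8% lower and the exonic length covered by peaks 28.7% lower (2395 kb in control, 1708 kb in cKO). Genes with 5 or more peaks numbered 172 in the control list and 87 in the cKO list. The giant cytoskeletal linker gene Dst had 17 control and 9 cKO peaks, Zfhx3 had 15 and 6, the atypical cadherin Fat1 had 14 and 5, Macf1 had 14 and 10, and the histone methyltransferase Kmt2d had 13 and 2. None of the 13 Kmt2d control peaks was overlapped by a cKO peak. The median fold enrichment was 19.3 (quartiles 10.1 and 46.7) in the control list and 13.2 (8.09 and 26.8) in the cKO list, each as the authors computed it within its own genotype. Folds below 10 were spaced in different steps in the 2 lists, as described below, so the medians need not share a scale. Median exonic peak width was nearly equal, at 211 and 210 nucleotides. Mettl3 and Mettl14, the 2 subunits of the methyltransferase core, had no peak in either list, which checks nothing about the deletion. Wtap, the adaptor of the methyltransferase complex, had 1 coding-sequence peak in the control list (fold 23.4) and none in the cKO list. With 1 list per genotype and unknown depth, no difference in number has a replicate error.

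Most control peaks had no cKO counterpart. Of the 8397 control peaks, 2829 (33.7%, 95% interval 32.7 to 34.7) were overlapped by a cKO peak, and 5568 were not. In the other direction, 2807 of 6709 cKO peaks (41.8%, 40.7 to 43.0) were overlapped by a control peak, and 3902 were not. The peak of highest fold in the control list, in the 3′ UTR of the Hippo kinase gene Lats2 (fold 3530), was among those without a counterpart. Peaks of the peptidyl-prolyl isomerase gene Ppig, the small GTPase gene Rnd3, Armcx4, Basp1 and Sec62 ranked high in both lists and did overlap. Their best folds in control and cKO were 684 and 914 for Ppig, 540 and 323 for Armcx4, 582 and 266 for Basp1, and 463 and 423 for Sec62. In Rnd3, a 3′ UTR peak of fold 1110 in control met a cKO peak of fold 10.2, and a 5′ UTR peak of fold 65.6 met one of 194. Among the 2799 genes with peaks in both lists, 2111 (75.4%) had at least 1 control peak that was overlapped. Requiring that the overlap cover at least 50% of both peaks lowered the control share to 22.0% and the cKO share to 27.5%.

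The cKO list held a larger share of 5′ UTR peaks and a smaller share of 3′ UTR peaks than the control list. Peaks in 5′ UTRs made up 2.32% of the control list (195 peaks, 2.01 to 2.67) and 7.56% of the cKO list (507 peaks, 6.94 to 8.22). Peaks in 3′ UTRs, where m6A is usually dense near the stop codon, made up 31.7% of the control list (2665 peaks, 30.7 to 32.7) and 23.9% of the cKO list (1605 peaks, 22.9 to 24.96). Coding sequence held nearly equal shares (4451 control peaks, 51.9 to 54.1%, and 3586 cKO peaks, 52.2 to 54.6%). Other exons, a class with no more specific part given by the authors, held 12.8% and 14.9%. Sparc and Timp2, which encode a matricellular glycoprotein and an inhibitor of matrix metalloproteinases, were among the genes with 5′ UTR peaks in the cKO list and no peak in the control list (fold 235 and 158).

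The transcript parts also differed in how often a control peak was met by a cKO peak. Control peaks in 3′ UTRs had a counterpart in 25.3% of cases (23.7 to 27.0), those in coding sequence in 38.4% (36.9 to 39.8) and those in 5′ UTRs in 76 of 195 cases (32.1 to 46.2%). Of the 507 cKO peaks in 5′ UTRs, 17.8% (14.5 to 21.4) were met by a control peak. Coding-sequence peaks spanned exon junctions far more often in the cKO list, a comparison chosen after the lists were seen. More than 1 exon block was present in 40.9% of control coding peaks (39.5 to 42.4) and 69.0% of cKO coding peaks (67.4 to 70.5). Among those with a counterpart the shares were 59.4% and 58.5%, whereas among those without one they were 29.4% in the control list and 78.1% in the cKO list. In 3′ UTRs, peaks of more than 1 block made up 9.61% and 8.41%.

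**Figure D1:**
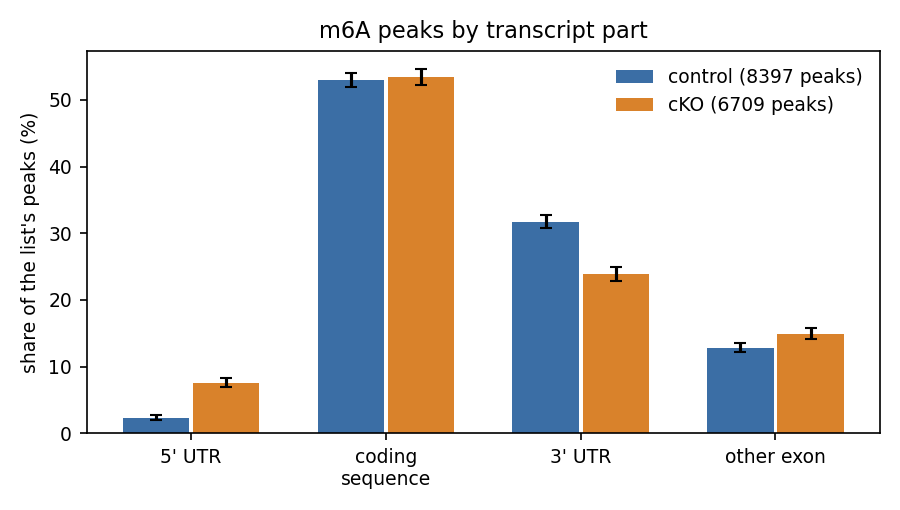
Share of each list's peaks (%, vertical axis) in each transcript part for the control list (8397 peaks) and the cKO list (6709 peaks), with exact 95% intervals for counting error as error bars. The 5′ UTR share is 2.32% in the control list and 7.56% in the cKO list, and the 3′ UTR share is 31.7% and 23.9%.

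At gene level, 2799 of the 6487 genes with any peak had peaks in both lists, 2187 in the control list alone and 1501 in the cKO list alone. The genes of highest fold in the control list alone were Ankrd50 (fold 2920, coding sequence, 5 peaks), Klhl9 (1650), Lypd1 (1260, 3′ UTR), the caspase-8 regulator gene Cflar (1160, coding sequence), the site-1 protease gene Mbtps1 (833), the m6A complex gene Rbm15 (796), the calcium/calmodulin kinase gene Camk2g (783, 3′ UTR) and the receptor tyrosine kinase antagonist gene Spry2 (756, coding sequence). The leading genes of the cKO list alone were Ube2l3 (3260), Ydjc (3200), Dazap2 (307), S100a11 (297), Rpl35a (262), Grap (238, 3′ UTR), Sparc (235, 5′ UTR) and Tmem176a (228). The Ube2l3 and Ydjc peaks lay at the same place on opposite strands (chromosome 16, from 17160044 to 17160372 for Ydjc), so the assignment to either gene is uncertain. Genes with more control peaks were more often found in the cKO list as well, from 47.3% (45.6 to 49.1) of genes with 1 control peak to 86.9% (81.0 to 91.5) of genes with 4 and 84.3% (78.0 to 89.4) of genes with 5 or more. Over all control genes, 56.1% also had a cKO peak. Where 2 folds of a gene are given in the gene lists that follow, they are the best control and the best cKO peak, and these overlap unless stated otherwise, as in 23 of the 44 named genes found in both lists. A gene in 1 list alone had no called peak in the other, which does not show that the mark was absent.

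Most Hippo pathway genes with a peak in control cells also carried one in cKO cells, while Lats2, the kinase gene that restrains the coactivator YAP, differed in its 3′ UTR. Of 26 Hippo genes with a control peak, 21 also had a cKO peak (80.8%, 60.6 to 93.4), including Lats1, Lats2, Nf2, Stk4, Fat1, Tead1 and Amotl2. Sav1 (fold 85.0), Csnk1e (16.5), Dchs1, Limd1 and Mob1b had a peak in the control list alone, and Stk3 (12.9) in the cKO list alone. Random lists gave 63.8% on average, and the Hippo list stood at percentile 97.475. Fat1 had its best control peak in coding sequence at fold 1990, overlapped by a cKO peak of fold 8. YAP and TEAD target genes stood at percentile 98.4, with 15 of 17 also in the cKO list, among them Ctgf, Cyr61, Ankrd1 and Amotl2. The best Amotl2 peaks, of fold 505 in the control 3′ UTR and 26.1 in the cKO 5′ UTR, lay apart, and the site called in both lists had folds of 11.7 and 17.4. Gadd45a (48.7) and Dock5 (36.6) were in the control list alone, and Nt5e (27.6) and Axl in the cKO list alone. When an overlapping peak and not any peak was required, the YAP and TEAD list stood at percentile 81.0.

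Lats2 had 8 control peaks and 5 cKO peaks, listed under 2 Ensembl identifiers of the same symbol (ENSMUSG00000021959 and ENSMUSG00000114942), so some places count under both. The 3′ UTR peak of fold 3530 lay on chromosome 14 from 57690859 to 57691367 on the minus strand and spanned 509 nucleotides. A cKO peak in the same 3′ UTR lay further downstream, from 57689692 to 57689841, at fold 15.4. Another control peak without a counterpart covered coding sequence from 57696125 to 57699694 in 3 blocks at fold 113. Further upstream, coding peaks of fold 184, 157 and 109 in control cells were overlapped by cKO peaks of fold 81.3, 46.2 and 13.6. At the 3′ end of the coding sequence, a control peak of fold 23.6 met a cKO peak of fold 30.5.

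**Figure D2:**
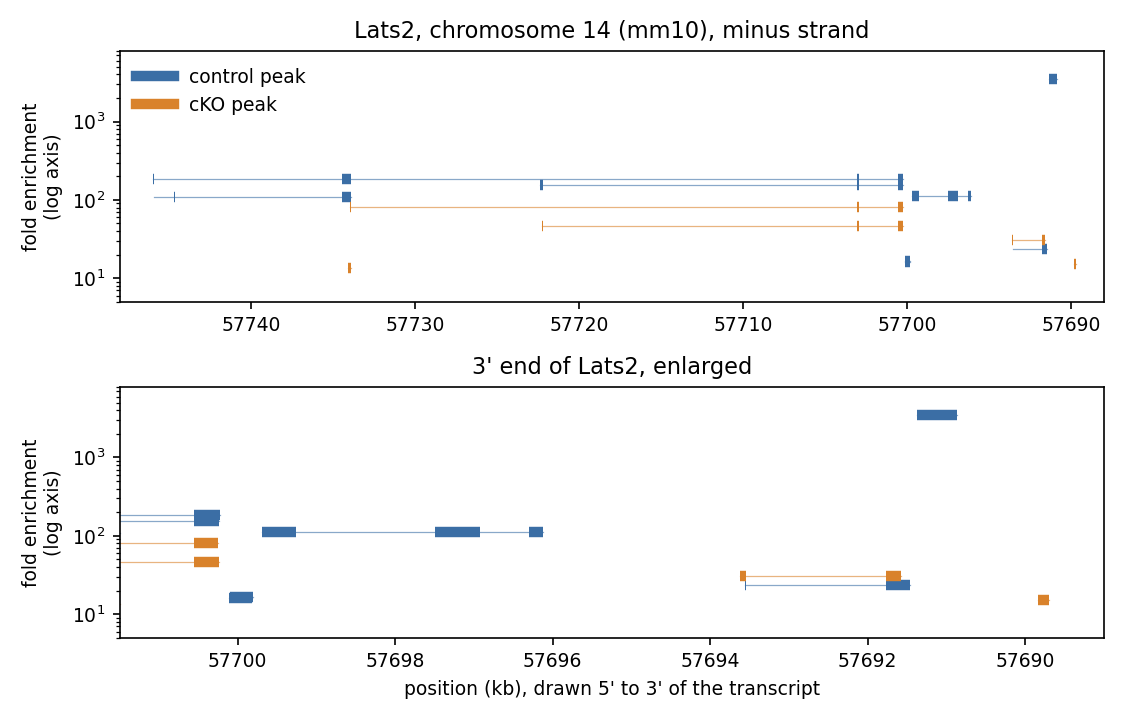
Map of all Lats2 peaks on chromosome 14 (mm10), with position in kb on the horizontal axis drawn 5′ to 3′ and the authors' fold enrichment on a log vertical axis. Thick bars are exon blocks and thin lines join blocks of a peak, in the whole gene (top) and at its 3′ end (bottom). The control peak of fold 3530 has no cKO peak below it.

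Genes of the fibrogenic programme mostly carried a peak in both genotypes. Of 21 markers of activated stellate cells and myofibroblasts with a control peak, 19 also had a cKO peak (90.5%, 69.6 to 98.8), against 59.9% in random lists (percentile 99.99). They included Acta2, Tagln, Des, Postn, Pdgfra and Pdgfrb. The collagen and matrix list behaved alike, with 23 of 26 genes in both lists (88.5%, 69.8 to 97.6; percentile 99.9), among them Col1a1, Col1a2 and Col3a1. Col8a1 (fold 586) and Col6a3 (93.2) and the crosslinking enzyme gene Lox (28.6) were in the control list alone. The calponin gene Cnn1 was there too, at fold 2.87. Hspg2, which encodes perlecan, had a best fold of 1210 in control and 104 in cKO and Itga5 374 and 60.7, in peaks that overlapped. The best control peaks of Col12a1 (819) and Pdgfra (423) had no counterpart, and the best cKO folds of these genes were 5.72 and 7.36. A further 10 matrix genes had a peak in the cKO list alone, including Fn1, Dcn, Bgn and Timp2, and so did 5 activation markers, including Sparc, Timp1 and S100a6. These were 27.8% (14.2 to 45.2) of the 36 matrix genes and 19.2% (6.55 to 39.4) of the 26 activation markers with any peak. Both intervals hold the 23.1% of all genes with a peak.

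Markers of quiescent stellate cells were divided between the lists. Of 14 with a control peak, 10 also had a cKO peak (71.4%, 41.9 to 91.6; percentile 79.8), including Plin2, Lhx2, Gata6 (201 in control, with no counterpart) and the retinoid receptor gene Rxra (1030 in control, met by a cKO peak of 5.73). Lrat, which encodes the enzyme that esterifies retinol for storage, had a 3′ UTR peak of fold 114 in the control list alone, and the retinoic acid receptor gene Rarb one of 53.5 in its 5′ UTR. A further 9 markers were in the cKO list alone, among them Colec11 (41.6), Reln, Hgf and Rgs5. These were 39.1% (19.7 to 61.5) of the 23 with any peak, an interval that holds the 23.1% of all genes with a peak. In TGF-beta and BMP signalling, 22 of 29 genes with a control peak also had a cKO peak (75.9%, 56.5 to 89.7; percentile 82.7). Smad1, Smad2, Smad3, Smad5, Smad6 and Smad7 were all in both lists. The SMAD corepressor gene Skil had best folds of 487 and 73.9, and the control peak of the activin receptor gene Acvr2a at 328 was met by a cKO peak of 10.4. Ltbp1 (339), the pseudoreceptor gene Bambi (117), Tgfbr2, Acvr1, Smurf1, Smurf2 and Zfyve16 had a peak in the control list alone, and Id3 (16.2), Fstl1 and Ltbp3 in the cKO list alone.

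Receptor tyrosine kinase, PI3K and MAPK signalling was the fixed list that stood lowest among its random lists. Of 39 genes with a control peak, 17 also had a cKO peak (43.6%, 27.8 to 60.4) and 22 did not, against 64.1% in random lists (percentile 0.315). Among the feedback inhibitors of the pathway, Spry2, Spry4, Spred1, Dusp1, Dusp5 and Dusp6 were in the control list alone, and Spry1, Spred2 and Dusp4 in both lists. Ligands, receptors and adaptors in the control list alone included Pdgfa (fold 504), Pdgfb, Met, Fgfr1, Insr, Irs1, Irs2, Gab1 and Grb2, and kinases included Braf, Map2k2, Akt2 and Pik3ca. Genes found in both lists included Dusp4, with best folds of 571 and 13.2, and Egfr. The best Egfr control peak, of fold 730, had no counterpart, and the site called in both lists had folds of 25 and 19.3. Mapk3 (60.3) was in the cKO list alone. An overlapping peak was present for 25.6% of these genes, against 51.7% in random lists (percentile 0.01). The percentile was 5.72 against random lists not matched on control peaks and fold.

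Wnt, Notch and hedgehog genes showed a similar share, with 10 of 21 also in the cKO list (47.6%, 25.7 to 70.2), at percentile 7.20. The Notch ligand gene Jag1 (fold 335), Notch1, Notch2 and Wnt5a (203) had a peak in the control list alone, while the receptor genes Fzd7 (263 and 9.10) and Lrp5 (213 and 19.9) were in both and Dkk3 (22.8) in the cKO list alone. With an overlapping peak required, the list stood at percentile 1.58.

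Transcription factor, cell cycle, chromatin and cytokine lists stood inside the range of random lists by the main measure. With an overlapping peak required, immediate early factors (percentile 97.525) and chromatin regulators (98.2) stood above it, and chromatin regulators also did against unmatched random lists (99.6). Among immediate early and stress transcription factors, 22 of 31 were in both lists (71.0%, 52.0 to 85.8; percentile 81.2), with Cebpd (506 in control, met by a cKO peak of 2.21), Nfe2l2 (501 and 19.1), Myc and Jun among them and Junb (459) and Bhlhe40 (440) in the control list alone. Cell cycle and p53 genes were in both lists in 10 of 15 cases (percentile 75.3). The p53 ligase gene Mdm2 (595 and 14.7) and Mki67 (280 and 78.0) were in both, Cdkn2b (393) and Mdm4 (339) in the control list alone and Ccne1 (44.5) in the cKO list alone. Chromatin regulators were in both lists in 32 of 42 cases (percentile 87.4), such as Kdm5a (689 and 122) and Crebbp (339 in control, with no counterpart). Kmt2c (34.6) and Setd1b (31.4) were in the control list alone and the DNA methyltransferase gene Dnmt1 (164) in the cKO list alone. Cytokine and JAK-STAT genes reached 14 of 22 (percentile 64.4), with the receptor genes Osmr (436 and 21.3) and Il6st in both. The best Il6st control peak, of fold 775, had no counterpart, and peaks of 14.5 and 6.88 shared no more than an end base. Tnfaip3 (85.4) and Traf6 (54.4) were in the control list alone and Stat5b (7.36) in the cKO list alone.

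Genes of the m6A machinery carried peaks themselves. Of 16 of its genes with a control peak, 11 also had a cKO peak (68.8%, 41.3 to 89.0; percentile 52.8). Rbm15b (513 and 17.7) and Zc3h13 were in both lists, together with the reader genes Ythdf2, Ythdf3 and Ythdc1. The best Zc3h13 control peak, of fold 322, was met by cKO peaks of 2.56 and 3.62, and its best cKO peak, of fold 238, by control peaks of 27 and 49.1. Besides Wtap and Rbm15, the reader gene Ythdf1 (101), Rbmx and the demethylase gene Alkbh5 had a peak in the control list alone, and the demethylase gene Fto (4.51, 5′ UTR) in the cKO list alone. Long non-coding RNAs were few, with 2 of 7 in both lists (28.6%, 3.67 to 71.0; percentile 9.48). Malat1 (15.5 and 7.85) and, at separate sites, Kcnq1ot1 (6.04 and 9.19) were in both, and Norad, listed as 2900097C17Rik (358), and Oip5os1, listed as 1700020I14Rik (67.2), were among the 5 in the control list alone.

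Cytosolic ribosomal protein transcripts ran the other way and were found mostly in the cKO list alone. Of 35 with any peak, 21 (60.0%, 42.1 to 76.1) were in the cKO list alone, against 23.1% of all genes with a peak. Only Rpl35 (fold 4.28) was in the control list alone. The remaining 13, including Rpl28 (54.2 in control, 216 in cKO) and Rps23 (47.1 and 8.83), were in both, which is 92.9% of the 14 with a control peak (66.1 to 99.8; percentile 99.985). Rps2 (121), Rplp0, Rpl5 and Rps6 were among the 21. Across the 16 lists with enough control genes, 1 stood below percentile 2.5 and 4 above 97.5. By the nominal limits, lists drawn at random would give 0.8 outside on average. In the simulation with 40 genes, 2 of 100 unchanged lists fell outside, so the actual average may be lower. Some lists share genes, such as Lats2 and Amotl2, and RNA abundance was not matched, so this is no test of an excess.

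Markers of other liver cells were sparse, except for those of endothelium. Of 8 liver endothelial genes with a control peak, 7 also had a cKO peak (87.5%, 47.3 to 99.7; percentile 93.0), including Cdh5 (737 and 136), Bmp2 (220 and 86.4), Pecam1 and Lyve1, with Kdr (10.5) in the control list alone. Hepatocyte genes with a peak were Ass1 (4.63 and 14.3) in both lists and Apoe and Serpina1b (49.8) in the cKO list alone. Macrophage markers gave Csf1r (15.7) in the control list and Cd68 (6.99) in the cKO list. The cholangiocyte marker Krt19 (11.4) appeared in the cKO list alone. Of the mesothelial markers, Cdh3 (9.26 and 10.3, at separate sites) was in both lists, and Efna5 (23.4) and Wt1 (12.9) were in the control list alone. Portal fibroblast markers were Thbd (137 and 15.4, at separate sites) in both, Fbln2 (20.9) in the control list alone and Ly6a (28.0) in the cKO list alone. Peak lists do not give the level of these RNAs, so the share of other cells is not known.

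**Figure D3:**
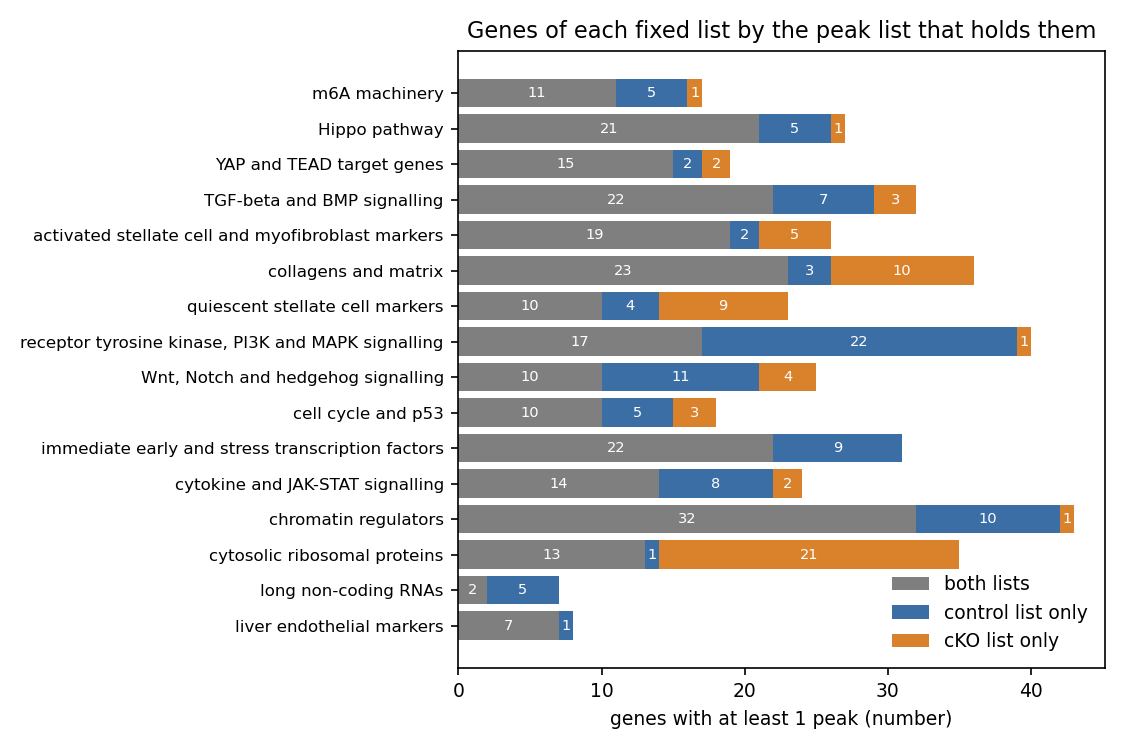
Number of genes with at least 1 peak (horizontal axis) in each of the 16 fixed gene lists that had 5 or more genes with a control peak, divided into genes found in both peak lists, in the control list only and in the cKO list only. Receptor tyrosine kinase, PI3K and MAPK signalling has 22 genes in the control list only, and cytosolic ribosomal proteins have 21 in the cKO list only.

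Peaks with a counterpart ranked higher on the whole, yet many control peaks of very high fold had none, as for Lats2, Ankrd50 and Klhl9. Within the control list, peaks with a counterpart had a median fold of 27.4 (quartiles 11.7 and 76.5) and those without one 16.5 (9.85 and 35.8). The probability that a peak with a counterpart outranked a peak without one was 0.600 by fold and 0.705 by the authors' p. In the cKO list the medians were 17.3 and 11.8, with probabilities of 0.608 and 0.722. Among the 10% of control peaks with the highest fold, 55.4% (51.9 to 58.8) had a counterpart, and among the 10% of cKO peaks with the highest fold 68.1% (64.4 to 71.6). The share did not climb steadily with fold. The lowest 10% of control peaks by fold had a counterpart in 38.5% of cases, above each of the next 7 steps of 10% (21.5 to 37.5%), and the lowest 10% of cKO peaks in 42.6%, above each of the next 6 (25.5 to 41.0%).

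**Figure D4:**
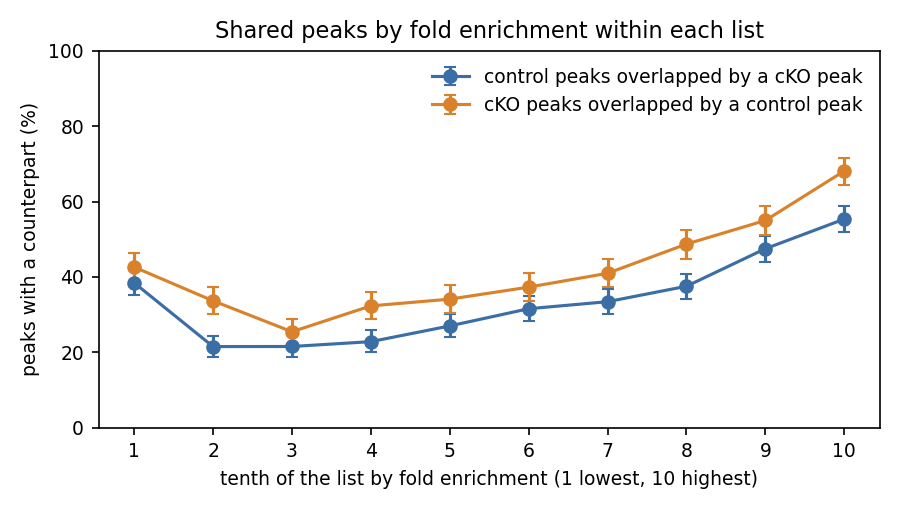
Share of peaks with a counterpart in the other list (%, vertical axis) by fold enrichment within each list in 10 equal steps (horizontal axis), with exact 95% intervals for counting error as error bars. The control list runs from 38.5% in the lowest step through 21.5% in the next to 55.4% in the highest.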

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

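No paired analysis was possible because each genotype has 1 list without values per replicate, and leaving out replicates was not possible for the same reason. The motif search and the gene count from exonic peaks alone were not run, the first without a genome sequence and the second because every peak has an exonic class. In all, 137 alternatives of 33 results were computed, and peak numbers stayed within 1.5 times throughout. Alternatives limited to genes with peaks in both lists, to a false discovery rate of 0.05, to protein-coding genes, to merging without strand and to length-matched random lists were added after the data were seen. What depth limits is unknown, as no read numbers were analysed here. For the values below that moved, the cause was not tested.

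The share of control peaks with a counterpart was 31.4% when the overlap had to cover 50% of the shorter peak, 22.0% for 50% of both peaks, 35.5% within 100 bp and 26.4% in the upper 50% of each list by fold. For cKO peaks these shares were 39.2%, 27.5%, 43.6% and 32.1%, and 34.9% at equal list length. In the upper 50% by fold, 5′ UTRs held 1.92% of control and 8.34% of cKO peaks, coding sequence 54.5% and 55.5%, cKO 3′ UTRs 21.9%, control other exons 11.8%, and 1326 genes had peaks in both lists. Among peaks with a counterpart, 5′ UTRs held 2.69% of control and 3.21% of cKO peaks, coding sequence 60.3% and 59.8%, control 3′ UTRs 23.9% and cKO other exons 13.0%. Among peaks without a counterpart, coding sequence held 49.3% of control and 48.9% of cKO peaks, control 3′ UTRs 35.7%, cKO 5′ UTRs 10.7% and cKO other exons 16.3%. In genes with peaks in both lists, coding sequence held 58.0% of control and 57.2% of cKO peaks, control 3′ UTRs 28.7% and other exons 10.7% and 11.1%. Among peaks with a counterpart the intervals of the 5′ UTR shares overlapped (2.12 to 3.35% in control, 2.59 to 3.93% in cKO).

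The probability that a peak with a counterpart outranks one without was 0.705 in the control list and 0.722 in the cKO list by log10 p, and 0.564 and 0.623 by fold with overlap of 50% of both peaks. With an overlapping peak required, YAP and TEAD targets fell inside the random range at percentile 81.0, while Hippo (97.8), Wnt, Notch and hedgehog (1.58), immediate early factors (97.5) and chromatin regulators (98.2) moved outside it. Against unmatched random lists, receptor tyrosine kinase, PI3K and MAPK signalling fell inside at 5.72, and Hippo (99.5), TGF-beta and BMP (98.5) and chromatin regulators (99.6) moved outside. At equal list length, Hippo stood at 97.53.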

Other observations

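Gene families were sorted by symbol after the lists had been seen, so the choice of these 20 families is not independent of the data. Ribosomal proteins, also among them, had been covered in part by a fixed list. Zinc finger and transporter genes with a control peak had a cKO peak less often than matched random genes. Of 117 genes with a Zfp symbol and a control peak, 35 also had a cKO peak (29.9%, against 56.0% in random lists matched on control peaks and fold, below all 10000 of them). Zfp664 (fold 138) and Zfp651 (129) had a peak in the control list alone, and Zfp451 was in both (470 and 6.86). Solute carriers gave 21 of 65 (32.3% against 54.7%, also below every random list), with the amino acid transporter genes Slc7a1 (218) and Slc36a1 (131) in the control list alone and Slc39a6 in both (1040 and 37.3). Zbtb genes gave 9 of 26 (34.6%, percentile 0.465).

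Other families stood at or near the upper end of the random lists. Of 16 proteasome genes with a control peak, 12 also had a cKO peak (percentile 98.5, with 48.5% in random lists), and 12 more, such as Psme3 (59.2) and Psmb3 (45.4), were in the cKO list alone. Nuclear genes of the respiratory chain gave 16 of 24 (66.7%, percentile 97.8) and a further 30 in the cKO list alone, among them Ndufa3 (81.6), Ndufb11 (54.8) and Cox17 (52.6). DEAD and DEAH helicase genes gave 23 of 31 (74.2%, percentile 99.3). Chaperones (24 of 34, percentile 96.7), splicing factors and hnRNPs (15 of 22, 95.5) and translation factors (20 of 29, 93.8) stayed inside the random range. All 6 mitochondrially encoded genes with a control peak also had a cKO peak, and 4 more were in the cKO list alone, at a median cKO fold of 3.28 over 13 peaks. Counting every Rpl and Rps symbol, 30 ribosomal protein genes were in the cKO list alone, 23 in both and 3 in the control list alone. Of the 19 families with a percentile, 3 stood below 2.5 and 5 above 97.5. The 5 include the ribosomal protein symbols, so that result is not separate from the fixed list.

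The 5′ UTR share was 3.25 times as high in the cKO list as in the control list. With both lists cut to 6709 peaks the ratio was 3.70. This cut could not have removed the difference and tests nothing, since it shortened the control list alone. That longer list held 195 5′ UTR peaks in all, against 507 in the cKO list. A difference in the genes listed is argued against, since the ratio was 2.81 among genes with peaks in both lists. A candidate explanation is m6Am, a mark next to the cap that METTL3 does not make and that m6A antibodies also bind. Of cKO 5′ UTR peaks without a counterpart, 51.9% (47.0 to 56.9) began within 100 bp of the gene's 5′ end, against 22.1% (16.4 to 28.7) of control 5′ UTR peaks, as this hypothesis predicts. The share was 51.8% for all cKO 5′ UTR peaks and 37.3% (26.4 to 49.3) for control ones with a counterpart. Yet a mark that METTL3 does not make should be in control cells too, and 17.8% of cKO 5′ UTR peaks were met by a control peak. Outside 5′ UTRs, 5.13% of cKO and 0.787% of control peaks began there. The comparison thus cannot decide for m6Am. More RNA 5′ ends in the cKO precipitated libraries for a technical reason would predict the same nearness to the 5′ end. It stays open, because library and genotype coincide and no value per library was analysed here.

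For the 5568 control peaks without a cKO counterpart, chance crossing of the calling threshold by weak peaks was weighed and may account for some. It predicts that nearly all strong peaks recur, whereas 55.4% of the 10% of control peaks with the highest fold did. In a test chosen after that result was seen, 66.9% (63.6 to 70.1) of the 10% of control peaks with the smallest p did, against 11.8% of the 10% with the largest p. Of the 10% of cKO peaks with the smallest p, 82.7% (79.6 to 85.5) had a control counterpart. The control shares argue against weak peaks as the whole account, as far as fold and p measure strength. With 1 list per genotype, how often strong peaks recur between calls of the same genotype is unknown. Of peaks with a fold below 10, 67.5% in the control list had a fold that was a whole multiple of 0.403 (within 0.005). In the cKO list 54.6% had a multiple of 0.368, and the medians for other steps were 1.02% and 1.48%. Low folds thus take few distinct values, spaced differently in each list. Above 10, steps were not counted, but equal folds could also come with equal log10 p, as in Wtap and Efna5 (23.4 and -6.76). What sets the steps was not tested, so a fold need not measure strength alike in all peaks. Loss of methylation, lower abundance of the transcript and a shallower or less efficient precipitation all stay open.

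The ribosomal protein genes, 21 of them found in the cKO list alone, were weighed against a signal at the cap and against carry-over of abundant RNA. The tests on the 21 genes by themselves were added after the others had been seen. A cap signal is argued against only as far as a start within 100 bp of the gene's 5′ end marks it. Of the cKO peaks of all 34 listed ribosomal protein genes with a cKO peak, 6.98% (3 of 43, 1.46 to 19.1) began there. Of the peaks of the 21 genes, 12% (3 of 25, 2.55 to 31.2) did. Carry-over could give weak peaks on any abundant RNA, and it is left undecided by median folds of 11.4 (bootstrap interval 9.26 to 23.8) for the 43 peaks and 11 (7.39 to 22.2) for the 25, since both intervals hold the 13.2 of all cKO peaks. A change of methylation with genotype was not tested and stays open beside it.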
